A study of Danio rerio with 14 samples.

How the data were processed

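Liver RNA of 14 samples from adult zebrafish was measured on a 3-prime Affymetrix zebrafish array with 1 colour. The labels describe each sample as the liver of an adult and place it in 1 of 4 groups by ahcy genotype and diet, with 4, 3, 5 and 2 arrays for regular-diet ahcy+/+, regular-diet ahcy+/-, overfed ahcy+/+ and overfed ahcy+/-. The deposited values are probe set summaries made by the authors; GCRMA and Partek are named in the submitters' processing notes, with no version, role or order. The values run from 0.464 to 14.74 with array medians of 5.95 to 6.12, and were read as the authors' log2 values from this range. They are not centred per probe set. The scanner files were not used here.

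The table holds 15617 probe sets. The 115 control probe sets were left out, which leaves 15502, and 368 that were not above 4 (log2) on at least 2 arrays were removed, so that 15134 were tested. Gene symbols came from the platform's own annotation, matched by Entrez ID to a reference gene table (10711 matched, 1 symbol updated); 10795 probe sets were assigned to 1 gene, 135 to several and 4572 to none. The 15134 probe sets represent 8699 genes with a probe set of their own.

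Group means were fitted to all 14 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust; 10 residual and 3.06 prior degrees of freedom), with no covariate, since the replicate numbers of the labels tie no samples together across groups. The contrasts were diet in ahcy+/+, diet in ahcy+/-, their mean, genotype on each diet, their mean, and the interaction. Benjamini-Hochberg adjustment ran over the tested probe sets within a contrast, with a threshold of 0.05. The number of arrays limits the precision. The level of ahcy was compared with a 2-sided exact permutation test. Genes in the real data are correlated, so the simulated recovery rates given next are not the power behind the calls here. The fit was tested on 20 simulated sets of 15134 probe sets with 200 changed ones and independent noise. For diet in ahcy+/+ it recovered 79.3% of probe sets changed by 1 and 96.6% of those changed by 2 (log2); for diet in ahcy+/- 58.7% and 90.4%; for genotype on the regular diet 73.1% and 95.0%; and for genotype after overfeeding 66.7% and 93.1%.

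Gene lists for liver pathways and for cell types that a liver sample could hold were fixed before the data were examined, as were the groups, tests, thresholds, the alternative settings and the rule for named genes. Of 33 lists, 32 had at least 5 measured members. Each gene was represented by its probe set with the highest mean. Lists were tested with camera (preset correlation 0.01), Benjamini-Hochberg adjusted over the lists within a contrast, and again with an estimated correlation and with fry. Members were counted over all probe sets and adjusted over the list alone.

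Named genes were, for diet in ahcy+/+, the 12 largest increases and the 12 largest decreases past the threshold, and for each other contrast the 6 largest of each. Only probe sets of exactly 1 gene with a symbol other than a clone or locus placeholder counted. Where fewer than 10 genes passed, all of those were named and then the genes with the smallest unadjusted p up to 10, as values with no call. In addition ahcy and up to 4 members per list with the smallest p were eligible. The mitotic genes, hspa5, xbp1, further members that passed with the cell cycle and endoplasmic reticulum stress lists, other probe sets of named genes, the shared vitellogenin probe sets and esr1 were named after their values were seen.

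These alternative settings were no low-value filter, a filter at 6 (log2), variance moderation with a trend and robust, a fit of the compared groups alone, array weights, quantile normalization, centring of each array on its median, the mean vitellogenin level as a covariate in place of the sex that the labels do not give, the replicate number as a block, 1 probe set per gene, and leaving out each array in turn. Fits without the 2 arrays highest in vitellogenin, fits with the mean levels of the pancreas and intestine lists as covariates, and list tests after both scalings were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.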

Results

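RNA from 14 liver samples of adult zebrafish was measured on a single-colour Affymetrix expression array. The fish were wild type (ahcy+/+) or heterozygous (ahcy+/-) for ahcy, which encodes the enzyme that hydrolyses S-adenosylhomocysteine, the by-product of methylation by S-adenosylmethionine. For a month, 1 tank holding both genotypes received a typical amount of food (regular diet) and 1 tank received food in excess (overfed). There were 4 arrays of regular-diet ahcy+/+ livers, 3 of regular-diet ahcy+/- livers, 5 of overfed ahcy+/+ livers and 2 of overfed ahcy+/- livers, and their number limits the precision. The labels give no sex. Each diet was 1 tank, so diet and tank cannot be told apart, and the p-values of the diet comparisons measure the spread among fish within tanks. Array medians lay between 5.95 and 6.12 on the log2 scale, and 15134 probe sets were tested. The first principal component carried 30.1% of the variance and separated the diets, with scores from -39.2 to -15.5 on the regular diet and from 14 to 37.4 after overfeeding. Array 9 of the regular-diet ahcy+/+ group scored -57.1 on the second component, which carried 19.6%. Its mean correlation with its own group was 0.912, against 0.942 to 0.974 for the other arrays.

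**Figure D1:**
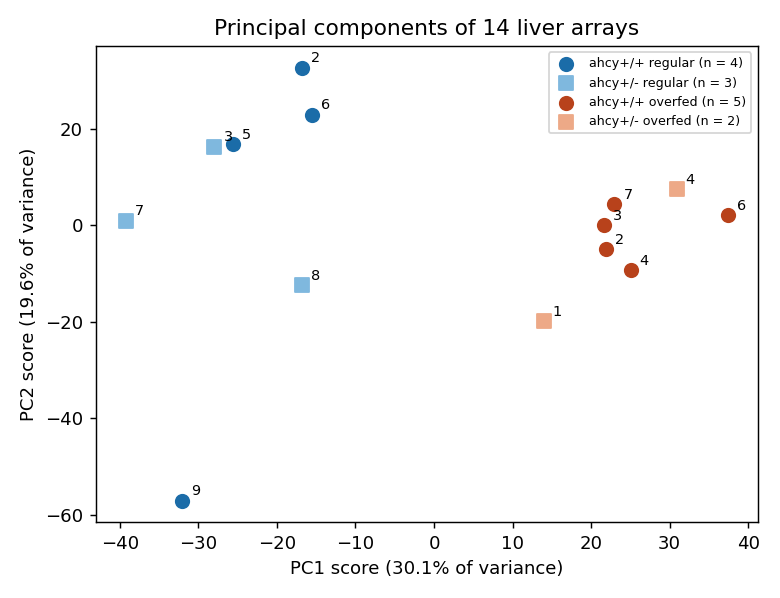
Scores of the 14 arrays on the first 2 principal components (30.1% and 19.6% of the variance), with colour and shape giving diet and genotype and numbers giving the replicate. All regular-diet arrays lie left of all overfed arrays, and regular-diet ahcy+/+ array 9 lies lowest.

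The level of ahcy itself was compared to see whether heterozygous livers held less of the transcript. Its mean was slightly higher in heterozygous livers on both diets, and neither difference passed the test. On the regular diet the ahcy probe set stood at 13.26 ± 0.07 (SD, n = 3) in ahcy+/- and 13.16 ± 0.06 (SD, n = 4) in ahcy+/+ livers, a log2 difference of 0.10 (2-sided exact permutation test, p = 0.143; the smallest p these groups allow is 0.0286). After overfeeding it stood at 13.29 ± 0.06 (SD, n = 2) and 13.21 ± 0.05 (SD, n = 5), a log2 difference of 0.08 (2-sided exact permutation test, p = 0.238; the smallest possible is 0.0476).

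The first diet comparison asked what a month of excess food did to the livers of ahcy+/+ fish. Overfed livers held 16.8-fold more transcript of ddit4, a stress-induced inhibitor of mTOR signalling, and 13.2-fold more of egln3, a prolyl hydroxylase that marks the hypoxia-inducible factor for degradation. They held 14.9-fold less cyp2r1, a vitamin D hydroxylase, and less of the DNA replication genes mcm3 and pcna. On the log2 scale ddit4 went from 6.0 ± 0.43 (SD, n = 4) to 10.07 ± 1.06 (SD, n = 5), egln3 from 7.16 ± 0.76 to 10.87 ± 0.57, and cyp2r1 from 8.82 ± 0.56 to 4.93 ± 0.28 in the same groups. Of 15134 probe sets, 681 passed an adjusted p of 0.05 in limma, 465 higher and 216 lower after overfeeding. At an unadjusted p under 0.05 there were 2980. With each array centred on its median, 628 were higher and 167 lower. The directions were more even without regular array 9 (716 higher, 626 lower) and with array weights (1066 and 883). The same held without the 2 arrays highest in vitellogenin (685 and 578) and with a vitellogenin covariate (746 and 551). The probe sets assigned to a single gene covered 335 higher and 158 lower genes, and 214 probe sets differed at least 2-fold, 152 higher and 62 lower.

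Among the 12 largest increases, ddit4 rose by 4.07 ± 0.51 (log2 difference ± SE; adjusted p = 0.00223), egln3 by 3.72 ± 0.36 (adjusted p = 0.000383) and the steroid dehydrogenase gene hsd17b3 by 3.23 ± 0.75 (adjusted p = 0.0287). Of genes that act in the response to cellular stress, ppp1r15a, which directs a phosphatase to the translation initiation factor eIF-2, rose by 2.85 ± 0.51 (adjusted p = 0.0108), and its 3 other probe sets rose by 2.61 to 2.72. Also among the 12 were tgfbi, a secreted matrix protein, which rose by 2.81 ± 0.60 (adjusted p = 0.0209), the metalloproteinase inhibitor gene timp2a, by 2.23 ± 0.37 (adjusted p = 0.00811) and p4ha1b, a subunit of the collagen prolyl hydroxylase, by 2.13 ± 0.19 (adjusted p = 0.000217). The fatty acid transport gene slc27a6 rose by 2.36 ± 0.26, the amino acid transporter gene slc43a2a by 2.14 ± 0.40, the mitochondrial cytochrome gene cyb5b by 2.11 ± 0.31, the transcription factor gene nfil3-5 by 2.52 ± 0.44 and ppdpfa by 2.24 ± 0.57, with adjusted p from 0.00081 to 0.0421.

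The 12 largest decreases were led by fabp2, the intestinal fatty acid binding protein, at -4.54 ± 0.81 (adjusted p = 0.011), cyp2r1 at -3.90 ± 0.31 (adjusted p = 0.000155) and the proto-oncogene mycb at -3.33 ± 0.58 (adjusted p = 0.0103). The growth hormone responsive inhibitor cisha differed by -2.74 ± 0.33 and the growth factor gene igf2b by -2.18 ± 0.48. Of genes for DNA replication and the cell cycle, mcm3 differed by -2.62 ± 0.38, pcna by -2.04 ± 0.37, cdca7a by -2.04 ± 0.39 and rgcc by -1.86 ± 0.26. A second mcm3 probe set differed by -0.08 with an adjusted p of 0.799. The sulfotransferase gene sult6b1 differed by -2.18 ± 0.48, rbm25a by -1.83 ± 0.47 and the apolipoprotein D gene apoda.2 by -1.82 ± 0.45. Every overfed array lay beyond every regular-diet array for 22 of these 24 genes. For a gene not chosen by its values, 0.794% of the splits of 9 arrays do so by chance in a given direction, but these genes were chosen for their differences, so the count is no test. For tgfbi and ppdpfa 4 of the 5 overfed arrays did. Leaving out single arrays ended the calls of hsd17b3 (3 of 14 fits), ppdpfa (10), rbm25a (9), tgfbi (4), sult6b1 (2), igf2b (3) and apoda.2 (7). The adjusted p was highest without regular array 2 for the first 3 (0.0838, 0.113 and 0.124) and without regular array 5 for the others (0.0693, 0.0786, 0.0757 and 0.112). The count was 267, 301 and 335 without regular arrays 2, 5 and 6, 1342 without regular array 9, and 391 and 253 without overfed arrays 4 and 6.

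**Figure D2:**
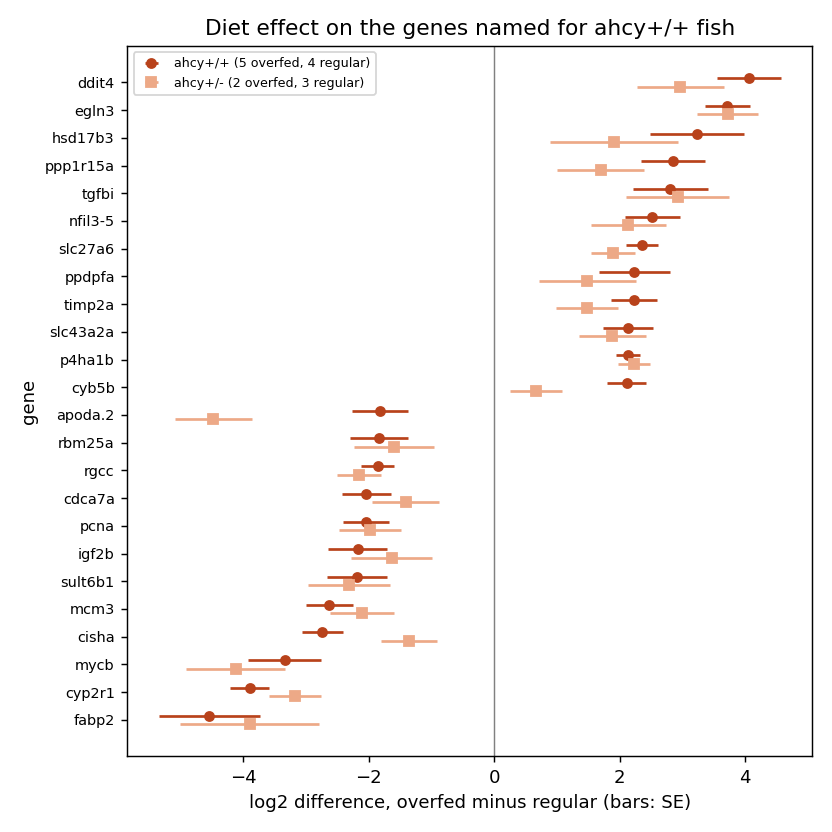
Log2 difference, overfed minus regular, of the 24 named genes in ahcy+/+ (dark circles, 5 against 4 arrays) and ahcy+/- livers (light squares, 2 against 3 arrays), with bars of 1 SE. All 24 genes differ in the same direction in both genotypes.

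Of 32 gene lists tested in this comparison, 9 rose and 2 fell by camera with a preset correlation. None passed with an estimated correlation, and 4 (cell cycle, fasting response, methionine metabolism and lipid droplet) passed by fry, which asks only whether a list's genes move one way. Cell cycle genes fell: 44 of 49 measured members were lower (median log2 difference -0.27, adjusted p = 2.04e-07; adjusted p = 0.174 with an estimated correlation). Of these, 10 passed over all probe sets and 13 adjusted over the list alone. The 10 were the helicase genes mcm2 (-1.42), mcm3 (-2.62), mcm4 (-1.51) and mcm5 (-1.49), the clamp gene pcna (-2.04), gins2 (-0.92), the ribonucleotide reductase gene rrm1 (-0.85), tyms (-1.17), ccnd1 (-1.08) and uhrf1 (-1.22). The other 39 members did not pass, with log2 differences from -0.90 for mki67 to 0.3 for top2a, 34 of them negative. Of the 10, mcm3, mcm4, pcna and rrm1 passed in all 14 fits that left out 1 array. The highest adjusted p was 0.0648 for mcm5, 0.0706 for mcm2, 0.0718 for gins2 and 0.128 for uhrf1 without regular array 5, 0.0968 for ccnd1 without regular array 2 and 0.0729 for tyms without overfed array 6. The list's mean level lay between 6.14 and 6.46 on the 7 regular-diet arrays and between 5.77 and 5.93 on the 7 overfed arrays. Markers of other tissues were lower in the same direction: the exocrine pancreas list averaged 9.98 ± 1.37 (SD, n = 4) on the regular diet and 9.14 ± 0.80 (SD, n = 5) after overfeeding in ahcy+/+ samples, and the intestine list 7.0 ± 1.72 and 5.11 ± 0.22.

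The endoplasmic reticulum stress list rose, with 24 of 31 members higher (median 0.47, adjusted p = 0.000168; adjusted p = 0.547 with an estimated correlation). It had 5 members higher over all probe sets, ddit4, the chaperone genes calr3b (1.41 ± 0.30) and dnajb11 (1.29 ± 0.28), manf (1.85 ± 0.40) and sel1l (0.74 ± 0.20), and 13 higher and 1 lower adjusted over the list alone. The main chaperone gene hspa5 (0.53) and the transcription factor gene xbp1 (0.01) did not pass. Proteasome genes rose, 29 of 40 being higher (median 0.18, adjusted p = 0.000278; adjusted p = 0.547 with an estimated correlation). They had 6 members past over all probe sets, led by psmd4b (0.91), and 9 adjusted over the list alone. Acute phase and complement genes rose, 25 of 27 being higher (median 0.36, adjusted p = 6.12e-05; adjusted p = 0.547 with an estimated correlation). Only the fibrinogen gene fga (0.53 ± 0.13) passed over all probe sets, and 5 members passed adjusted over the list alone. The adjusted p was 0.07 for dnajb11 and for manf without regular array 2, 0.06 for calr3b without regular array 6, and 0.116 for sel1l and 0.102 for fga without overfed array 6. After quantile normalization the proteasome list stood at 0.139. With the mean levels of the pancreas and intestine lists as covariates the acute phase list did not pass.

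Metabolic lists rose as well. The gluconeogenesis and fasting list had 14 of 20 members higher (median 0.31, adjusted p = 0.000696; adjusted p = 0.174 with an estimated correlation). Its 3 members past over all probe sets were pck2 (0.67), which makes phosphoenolpyruvate, the tyrosine aminotransferase gene tat (0.65) and cebpb (1.17), and 9 passed adjusted over the list alone. Cholesterol synthesis had 10 of 12 members higher (median 1.40, adjusted p = 0.00498; adjusted p = 0.547 with an estimated correlation). It had insig1 (1.44 ± 0.32) and acat2 (1.56 ± 0.40) past over all probe sets, and 5 members higher and 1 lower adjusted over the list alone. The methionine and one-carbon list, to which ahcy belongs, had 20 of 27 members higher (median 0.17, adjusted p = 0.0116; adjusted p = 0.243 with an estimated correlation). The cystathionine synthase gene cbsb rose by 1.54 ± 0.18 (adjusted p = 0.00165) and the adenosine kinase gene adkb by 0.62 ± 0.12. The DNA methyltransferase gene dnmt1 (-0.49) and the spermine synthase gene sms (-0.37) fell. Adjusted over the list alone, 6 members were higher and 2 lower. Lipid droplet genes had 6 of 7 members higher (median 0.54, adjusted p = 0.00903; adjusted p = 0.48 with an estimated correlation), with the lipase gene lipea (0.54) past over all probe sets and 3 members adjusted over the list alone. The adjusted p was 0.123 for acat2 without regular array 2, 0.0807 for insig1, 0.141 for sms and 0.0955 for lipea without regular array 5, 0.114 for dnmt1 without regular array 6 and 0.0636 for cebpb without overfed array 6. The methionine list stood at 0.059 without regular array 9 and at 0.181 after quantile normalization, and the lipid droplet list at 0.063 after that normalization. With the mean levels of the pancreas and intestine lists as covariates the methionine list did not pass either.

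Fatty acid oxidation genes had 22 of 26 members higher (median 0.29, adjusted p = 0.00416; adjusted p = 0.582 with an estimated correlation). The only member past over all probe sets, and the only one adjusted over the list alone, was the peroxisomal gene ehhadh, which was lower (-0.60 ± 0.14). The antioxidant list had 21 of 29 members higher (median 0.15, adjusted p = 0.0367; adjusted p = 0.547 with an estimated correlation). Its member keap1a, the inhibitor of the antioxidant regulator NRF2, rose by 1.84, and 2 members passed adjusted over the list alone. Intestine genes fell, 12 of 13 being lower (median -1.96, adjusted p = 0.00269; adjusted p = 0.547 with an estimated correlation), with fabp2 the only member past over all probe sets or adjusted over the list alone. The adjusted p was 0.151 for the intestine and 0.664 for the antioxidant list without regular array 9, 0.0576 for fatty acid oxidation without overfed array 3 and 0.0901 for ehhadh without regular array 5. The antioxidant call also ended without regular array 2 or overfed array 6 or 7. After quantile normalization the antioxidant (0.619) and fatty acid oxidation lists (0.157) did not pass. Nor did the antioxidant list with the mean levels of the pancreas and intestine lists as covariates.

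**Figure D3:**
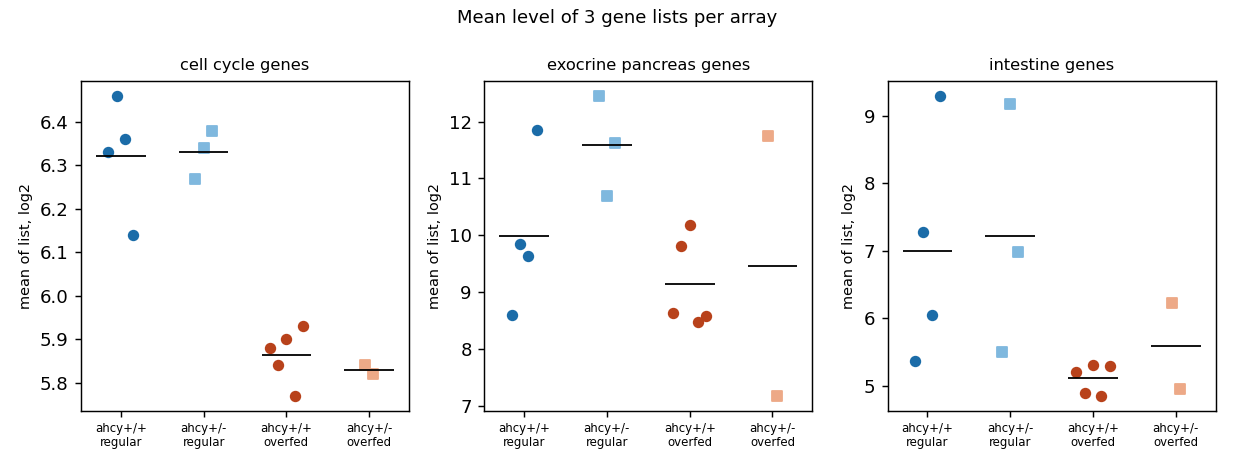
Mean log2 level of the cell cycle, exocrine pancreas and intestine lists on each array, by group, with lines at the group means. Cell cycle means of all overfed arrays (5.77 to 5.93) lie below those of all regular-diet arrays (6.14 to 6.46). Over both genotypes the pancreas and intestine means overlap between diets. In ahcy+/+ samples alone the intestine means do not overlap (4.85 to 5.31 overfed, 5.37 to 9.29 regular).

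Several lists that did not pass as a whole held members that did. Of amino acid catabolism genes (adjusted p = 0.0957), tdo2a (0.97), got2b (0.87) and tat (0.65) rose, and 7 members were higher and 1 lower adjusted over the list alone. Of growth hormone and insulin genes (adjusted p = 0.469), cisha, igf2b and the growth hormone receptor gene ghrb (-0.91) fell. Adjusted over the list alone, 3 were higher and 3 lower. Fatty acid and triglyceride synthesis genes (adjusted p = 0.263) went both ways, with acaca (1.56) and me1 (0.99) higher and mid1ip1l (-1.48) and lpin1a (-0.88) lower. Adjusted over the list alone, 3 were higher and 2 lower. Of inflammatory genes (adjusted p = 0.145), junbb (1.85), junba (1.72) and cebpb rose and socs1a (-1.07) fell. Adjusted over the list alone, 4 were higher and 1 lower. Of circadian genes (adjusted p = 0.457), nfil3-5 and cry4 (0.98) rose and nfil3-6 (-1.52) fell. Adjusted over the list alone, 3 were higher and 1 lower. Of matrix, stellate and endothelial genes (adjusted p = 0.798; median -0.07, mean 0.06), timp2a, tgfbi and kdrl (0.56) rose, and 3 passed adjusted over the list alone. The adjusted p was 0.0702 for acaca, 0.0705 for junba, 0.103 for socs1a, 0.0757 for igf2b, 0.0693 for tgfbi and 0.0757 for kdrl without regular array 5, and 0.125 for me1 and 0.0636 for cebpb without overfed array 6.

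Of xenobiotic genes (adjusted p = 0.611; median -0.03, mean 0.02), the sulfotransferase genes sult1st1 (1.24) and sult1st3 (1.0) rose and cyp3a65 (-0.79) fell, 2 higher and 1 lower adjusted over the list alone too. Of oxidative phosphorylation genes (adjusted p = 0.173) the cytochrome c gene cycsb (1.05) and uqcrfs1 (0.60) rose, and 2 passed adjusted over the list alone. Of hepatocyte genes (adjusted p = 0.116) the transcription factor gene hnf4a (0.67) rose, the only one adjusted over the list alone as well. In glycolysis (adjusted p = 0.347) pgam1a (0.73) was higher and eno1b (-0.49) lower, each also adjusted over the list alone. Of the vitellogenin and oestrogen list (adjusted p = 0.457; median 0.02, mean -0.06) the protease gene ctsd (0.70) rose, 1 adjusted over the list alone. No member passed over all probe sets in limma among exocrine pancreas (adjusted p = 0.0965, 17 of 18 lower), skeletal muscle (0.0727), leukocyte (0.115), endocrine pancreas (0.115), apolipoprotein (0.131; median 0.17, mean -0.11), erythrocyte (0.263), ovary (0.321), ribosomal protein (0.375), cholangiocyte (0.478) and bile acid genes (0.561; median 0.16, mean -0.18). The adjusted p was 0.0566 for sult1st1, 0.0575 for sult1st3, 0.0563 for uqcrfs1 and 0.0732 for hnf4a without regular array 2, 0.0684 for cyp3a65 without regular array 6, and 0.0938 for eno1b and 0.0893 for pgam1a without overfed array 6.

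The second diet comparison asked the same of ahcy+/- livers. Overfed ahcy+/- livers held 13.2-fold more egln3 and 4.69-fold more p4ha1b, both prolyl hydroxylase genes, and 9.01-fold less cyp2r1. The levels of egln3 were 7.13 ± 0.50 (SD, n = 3) on the regular diet and 10.85 ± 0.06 (SD, n = 2) after overfeeding. Of the probe sets that passed, that of the apolipoprotein D gene apoda.2 differed most, from 10.14 ± 1.36 to 5.67 ± 0.55 in the same groups. In limma 15 probe sets passed, 10 higher and 5 lower, and 2145 had an unadjusted p under 0.05. With arrays centred on their medians, 58 were higher and 6 lower, whereas lower calls were the more numerous with a vitellogenin covariate (30 higher, 38 lower) and without the 2 arrays highest in vitellogenin (20 and 38). That scaling moved the median of all probe sets by 0.11 from -0.09. The higher genes named were egln3 (3.72 ± 0.48, adjusted p = 0.00979), p4ha1b (2.23 ± 0.26), hif1an, which hydroxylates the hypoxia-inducible factor (1.81 ± 0.29), the kinase gene limk2 (1.81 ± 0.29), erf (1.64 ± 0.20) and tiparp (1.5 ± 0.19). The lower ones were apoda.2 (-4.47 ± 0.61, adjusted p = 0.0124), cyp2r1 (-3.17 ± 0.42), rgcc (-2.16 ± 0.35), the lipogenesis regulator mid1ip1l (-1.92 ± 0.28) and trim47 (-0.93 ± 0.15). Leaving out 1 array ended the calls of hif1an, limk2 and rgcc in 10 of 14 fits and that of trim47 in 9, with an adjusted p of up to 0.174, 0.196, 0.2 and 0.254. The calls of the other genes named ended without overfed ahcy+/- array 4 (0.124 to 0.139) and, except for erf, without overfed ahcy+/- array 1. No probe set passed without overfed ahcy+/- array 4, 4 did without overfed ahcy+/- array 1, 91 without regular ahcy+/+ array 9, 41 without regular ahcy+/- array 8 and 28 without overfed ahcy+/+ array 7. The count was 9 without regular ahcy+/+ array 2, 5 or 6, regular ahcy+/- array 3 or overfed ahcy+/+ array 2, and 0 in a fit of these 2 groups alone.

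Of the 32 lists, 9 rose and 5 fell in this comparison; 2 of them (cell cycle and skeletal muscle) passed by fry. The adjusted p with an estimated correlation was 0.27 for the cell cycle, skeletal muscle, lipid droplet and fasting lists, 0.661 for intestine and 0.607 for the others, which leaves 0 calls. Cell cycle genes fell, 46 of 49 being lower (median -0.38, adjusted p = 1.44e-06; adjusted p = 0.27 with an estimated correlation). Among 14 that passed adjusted over the list alone were rrm1 (-0.80), mcm3 (-2.11), pcna (-1.98) and mcm4 (-1.21), though 0 did over all probe sets. All 17 skeletal muscle genes were lower (median -0.65, adjusted p = 1.01e-05; adjusted p = 0.27 with an estimated correlation), 6 of them adjusted over the list alone, with tnnt3a at -0.73 and actc1b at -1.31. All 18 exocrine pancreas genes were lower (median -2.36, adjusted p = 0.000712; adjusted p = 0.607 with an estimated correlation), 0 of them adjusted over the list alone. Their mean stood at 11.59 ± 0.88 (SD, n = 3) on the regular diet and at 7.18 and 11.74 on the 2 overfed arrays. Intestine genes had 12 of 13 members lower (adjusted p = 0.033; adjusted p = 0.661 with an estimated correlation), 2 adjusted over the list alone. Ovary genes had 13 of 15 lower (adjusted p = 0.0461; adjusted p = 0.607 with an estimated correlation), 0 adjusted over the list alone.

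Higher in overfed ahcy+/- livers were 22 of 26 fatty acid oxidation genes (median 0.37, adjusted p = 1.01e-05; adjusted p = 0.607 with an estimated correlation). The enzyme gene ehhadh (-0.80) was the 1 member that passed adjusted over the list alone. Acute phase genes had 23 of 27 members higher (adjusted p = 8.54e-05; adjusted p = 0.607 with an estimated correlation), and 0 passed adjusted over the list alone. Endoplasmic reticulum stress genes had 23 of 31 higher (adjusted p = 0.000984; adjusted p = 0.607 with an estimated correlation), with ddit4 (2.97) the 1 adjusted over the list alone. Lipid droplet genes had 7 of 7 higher (adjusted p = 0.00212; adjusted p = 0.27 with an estimated correlation) and proteasome genes 28 of 40 (adjusted p = 0.00321; adjusted p = 0.607 with an estimated correlation), each with 0 adjusted over the list alone. Cholesterol genes had 10 of 12 higher (adjusted p = 0.00316; adjusted p = 0.607 with an estimated correlation), with insig1 (1.85) the 1 adjusted over the list alone. Fasting genes had 13 of 20 higher (adjusted p = 0.00461; adjusted p = 0.27 with an estimated correlation), with tat (0.95), pck2 (0.80) and g6pc1a.2 (0.64) the 3 adjusted over the list alone. The vitellogenin and oestrogen list had 8 of 9 higher (adjusted p = 0.00574; adjusted p = 0.607 with an estimated correlation), with ctsd (0.91) the 1 adjusted over the list alone. Erythrocyte genes had 9 of 15 higher (adjusted p = 0.0335; adjusted p = 0.607 with an estimated correlation), with nt5c2l1 (1.88) the 1 adjusted over the list alone. Without overfed ahcy+/- array 4 the pancreas list turned higher (adjusted p = 0.625), erythrocytes stood at 0.199 and the intestine, ovary and proteasome calls ended. The vitellogenin list stood at 0.178 without overfed ahcy+/- array 1. Without regular ahcy+/- arrays 7, 3 and 8 the intestine, proteasome and ovary lists stood at 0.577, 0.148 and 0.328. Leaving out array 3 ended the erythrocyte call too, and the ovary call ended in 7 of the 14 fits that left out 1 array.

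The diet effects of the 2 genotypes, which share no array but come from the same 2 tanks, ran in parallel. Across the 15134 probe sets, which are not independent replicates, their Pearson correlation was 0.729 and their Spearman correlation 0.653. Of the 681 probe sets called in ahcy+/+ livers, 672 (98.7%) had the same sign in ahcy+/- livers, against 74.98% of all probe sets. All 15 called in ahcy+/- livers, among them egln3, p4ha1b, hif1an, cyp2r1, rgcc and apoda.2, were also called in ahcy+/+ livers with the same sign. If calls were independent, 0.675 shared calls would arise by chance. They are not independent, since both comparisons take the spread of each probe set from all arrays. The overlap is therefore no independent replication, and the chance value is no test. In a fit of the compared groups alone, 0 probe sets were called in ahcy+/- livers.

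Averaged over the genotypes, the diet comparison gave more calls than in either genotype alone. The prolyl hydroxylase gene egln3 rose by 3.72 ± 0.30 (log2 difference ± SE; adjusted p = 5.03e-05), ddit4 by 3.52 ± 0.43 and tgfbi by 2.87 ± 0.51. Rising as well were fdps (3.28 ± 0.92) and fdft1 (2.61 ± 0.74), enzymes of sterol synthesis, and angptl4, a lipoprotein lipase inhibitor (2.80 ± 0.83). Lower were fabp2 (-4.22 ± 0.69), mycb (-3.72 ± 0.49), cyp2r1 (-3.53 ± 0.26, adjusted p = 2.15e-05), the chitinase gene chia.3 (-3.48 ± 1.01), apoda.2 (-3.14 ± 0.38) and nr0b2a, a nuclear receptor that represses bile acid synthesis (-2.56 ± 0.68). In limma 1564 probe sets passed, 883 higher and 681 lower, with 4189 at an unadjusted p under 0.05. With arrays centred on their medians 1286 were higher and 364 lower, whereas lower calls were the more numerous with a vitellogenin covariate (1076 higher, 1384 lower), with array weights (1352 and 1458) and without regular ahcy+/+ array 9 (1155 and 1164). Without overfed ahcy+/- array 4 the count was 538 and the adjusted p was 0.141 for fdps, 0.147 for fdft1, 0.174 for chia.3 and 0.158 for nr0b2a. Without overfed ahcy+/- array 1 the count was 819 and angptl4 stood at 0.186. Leaving out 1 array ended these calls in 10 of 14 fits for fdps and fdft1, 12 for chia.3, 4 for nr0b2a and 11 for angptl4. The count was 941 without regular ahcy+/- array 3 and 2319 without regular ahcy+/+ array 9.

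In the average, 7 lists rose and 4 fell, and 5 passed by fry (cell cycle, skeletal muscle, fasting, lipid droplet and methionine). Cell cycle genes fell (adjusted p = 1.64e-07; adjusted p = 0.234 with an estimated correlation), 15 over all probe sets and 24 adjusted over the list alone. All 17 skeletal muscle genes were lower (adjusted p = 0.000399; adjusted p = 0.36 with an estimated correlation), tnnt3a (-0.50), actc1b (-1.01) and tpma (-0.44) passing over all probe sets and 6 adjusted over the list alone. Fatty acid oxidation genes rose (adjusted p = 4.24e-05; adjusted p = 0.507 with an estimated correlation), with 5 past over all probe sets, hadhb (0.83) and acadvl (1.01) among them, and 7 adjusted over the list alone, while ehhadh fell by 0.70. The fasting list rose (adjusted p = 0.00117; adjusted p = 0.234 with an estimated correlation), with 7 past over all probe sets, such as tat (0.80), pck2 (0.73) and gpt (1.02), and 8 adjusted over the list alone. Cholesterol genes rose (adjusted p = 0.00165; adjusted p = 0.507 with an estimated correlation), with insig1 (1.65), acat2 (1.51), fdps and fdft1 past over all probe sets and 6 higher and 1 lower adjusted over the list alone.

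Acute phase genes rose (adjusted p = 1.62e-05; adjusted p = 0.507 with an estimated correlation), the fibrinogen genes fga, fgb and fgg and the plasminogen gene plg passing over all probe sets and 7 adjusted over the list alone. The endoplasmic reticulum stress list rose (adjusted p = 0.000149; adjusted p = 0.507 with an estimated correlation), 9 higher and 1 lower over all probe sets and 14 and 4 adjusted over the list alone. Proteasome genes rose (adjusted p = 0.000399; adjusted p = 0.559 with an estimated correlation), 8 higher and 1 lower both over all probe sets and adjusted over the list alone. Lipid droplet genes rose (adjusted p = 0.00165; adjusted p = 0.35 with an estimated correlation), with lipea (0.50) and lpla (0.55) past over all probe sets and 3 adjusted over the list alone. Exocrine pancreas genes were lower in 17 of 18 cases (adjusted p = 0.00309; adjusted p = 0.668 with an estimated correlation), 0 adjusted over the list alone, and stood at an adjusted p of 0.437 without overfed ahcy+/- array 4. Intestine genes fell (adjusted p = 0.00455; adjusted p = 0.559 with an estimated correlation), fabp2 and alpi.1 (-0.31) over all probe sets and 3 adjusted over the list alone.

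The genotype comparisons asked what carrying 1 mutated ahcy copy did within a tank. On the regular diet the apolipoprotein D gene apoda.2 stood at 10.14 ± 1.36 (SD, n = 3) in ahcy+/- and 7.26 ± 0.71 (SD, n = 4) in ahcy+/+ livers, a log2 difference of 2.89 ± 0.51 (SE). The phosphatidylethanolamine methyltransferase gene pemt, whose product uses S-adenosylmethionine, differed by 0.74 ± 0.17 and the chemokine gene cxcl12a by 0.94 ± 0.23. None of these passed: in limma 0 probe sets were called, with 459 at an unadjusted p under 0.05 where chance gives 757, and every adjusted p was 1. That unadjusted count depended on the arrays. It was 357 without regular ahcy+/- array 8, 932 without regular ahcy+/+ array 9 and 1062 without regular ahcy+/- array 7. With array weights it was 1197. In each of these fits 0 probe sets were called. The other genes with the smallest p were dact2 (0.51), naalad2 (0.53), b3gnt7 (0.57), fgf10a (1.29), ftsj1 (-0.63), gstcd (-0.36) and the hepatic lipase gene lipca (-0.47).

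By list, 6 were higher and 1 lower in regular-diet ahcy+/- livers, and 0 passed by fry. All 18 exocrine pancreas genes were higher (median 1.74, adjusted p = 9.54e-07; adjusted p = 0.776 with an estimated correlation), sycn.2 by 2.11 and cpa1 by 2.34, with group means of 11.59 ± 0.88 (SD, n = 3) and 9.98 ± 1.37 (SD, n = 4). Skeletal muscle genes were higher in 16 of 17 cases (adjusted p = 7.76e-06; adjusted p = 0.332 with an estimated correlation), with mylpfa at 0.99 and acta1a at 0.63. Oxidative phosphorylation genes were higher in 75 of 84 cases (median 0.16, adjusted p = 7.76e-06; adjusted p = 0.776 with an estimated correlation), with sdhb at 0.36. Antioxidant genes were higher in 27 of 29 cases (adjusted p = 0.0318; adjusted p = 0.776 with an estimated correlation), methionine genes in 21 of 27 (adjusted p = 0.047; adjusted p = 0.39 with an estimated correlation) and glycolysis genes in 21 of 25 (adjusted p = 0.047; adjusted p = 0.332 with an estimated correlation). Ribosomal protein genes were lower in 39 of 67 cases (median -0.01, adjusted p = 0.0469; adjusted p = 0.92 with an estimated correlation). Over all probe sets 0 members passed, and adjusted over the list alone only pemt did. Leaving out 1 array ended the calls for antioxidant (4 of 14 fits; 0.611 without regular ahcy+/+ array 9), oxidative phosphorylation (2 fits; 0.497 without the same array), glycolysis (6 fits), methionine (8 fits) and skeletal muscle (1 fit; 0.67, 0.262 and 0.147 without regular ahcy+/- array 7), and ribosomal proteins (7 fits; 0.65 without regular ahcy+/- array 8), not for exocrine pancreas. After quantile normalization the antioxidant (0.127), glycolysis (0.162), methionine (0.256) and oxidative phosphorylation lists (0.0953) did not pass.

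Between genotypes after overfeeding, the gene with the smallest p was hnf4a, a transcription factor of hepatocytes. It stood at 6.67 ± 0.11 (SD, n = 2) in ahcy+/- and 7.76 ± 0.30 (SD, n = 5) in ahcy+/+ livers, a log2 difference of -1.09 ± 0.18 (SE; limma adjusted p = 0.631). In limma 0 probe sets passed, with 260 at an unadjusted p under 0.05. The next genes were trim47 (-0.56), tmco1 (-0.67), clcn7 (0.63), magoh (-0.62), sall1a (1.40), vps33a (0.57), pik3c2a (0.60), bcl6ab (-0.55) and zic2b (-0.40), each with an adjusted p of 1. Fatty acid oxidation genes were higher in 23 of 26 cases (median 0.16, adjusted p = 0.000686; adjusted p = 0.993 with an estimated correlation), with acsl1a at 0.30 and cpt1ab, of the carnitine palmitoyltransferases that carry fatty acids into mitochondria, at 1.0. In this list 0 passed over all probe sets or adjusted over the list alone. The list's adjusted p was 0.29 without overfed ahcy+/+ array 7. There were 4 calls over all probe sets without overfed ahcy+/- array 1.

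Averaged over the diets, hnf4a was again first between genotypes, at -0.63 ± 0.12 (SE), followed by apoda.2 at 1.56 ± 0.38, lipca (-0.34), ndrg4 (0.48), cxcl12a (0.62), cxcl14 (0.45), prelid1a (-0.34), lrig1 (0.44), dtx4a (-0.44) and trim47 (-0.31). None passed, all having an adjusted p of 0.999, and in limma 0 probe sets were called with 371 at an unadjusted p under 0.05. By list, exocrine pancreas genes were higher in ahcy+/- livers in 18 of 18 cases (adjusted p = 0.000118; adjusted p = 0.984 with an estimated correlation). Higher too were fatty acid oxidation genes in 21 of 26 cases (adjusted p = 0.0159; adjusted p = 0.984 with an estimated correlation), oxidative phosphorylation genes in 67 of 84 (adjusted p = 0.0159; adjusted p = 0.984 with an estimated correlation), apolipoprotein genes in 13 of 16 (adjusted p = 0.0433; adjusted p = 0.806 with an estimated correlation) and skeletal muscle genes in 13 of 17 (adjusted p = 0.0433; adjusted p = 0.984 with an estimated correlation). Ribosomal protein genes were lower in 50 of 67 cases (adjusted p = 0.0159; adjusted p = 0.984 with an estimated correlation). In these lists 0 members passed over all probe sets or adjusted over the list alone. Without overfed ahcy+/- array 1 the pancreas list turned lower (0.191) and 2 probe sets were called. Calls ended in 5 of 14 fits for fatty acid oxidation and 10 for skeletal muscle (0.344 and 0.474 without regular ahcy+/- array 7), 6 for ribosomal proteins (0.191 without regular ahcy+/- array 8), 6 for oxidative phosphorylation (0.744 without regular ahcy+/+ array 9) and 8 for apolipoproteins (0.483 without overfed ahcy+/- array 4).

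The interaction asked whether the diet effect differed between the genotypes. Among the genes with the smallest p, the log2 difference between the diet effects, ahcy+/- minus ahcy+/+, was 2.45 ± 0.55 (SE) for ifi44a6, of an interferon-induced family, and -1.06 ± 0.25 for pemt. The group means of ifi44a6 (3.375 to 4.928) and of dact2 (3.732 to 4.336) lay near the low-value limit of 4. The hepatocyte factor hnf4a stood at -0.92 ± 0.24, and dact2 (-0.64), gtf3c2 (-0.63), ftsj1 (0.92), trim55b (-0.56), sec22a (0.93), tfb2m (-0.76) and clcn7 (0.77) followed. Each had an adjusted p of 1, and in limma 0 probe sets were called with 289 at an unadjusted p under 0.05. Without overfed ahcy+/- array 1 there were 4 calls. By list, all 17 skeletal muscle genes (median -0.43, adjusted p = 8.71e-05; adjusted p = 0.698 with an estimated correlation), 72 of 84 oxidative phosphorylation genes (adjusted p = 0.00134; adjusted p = 0.974 with an estimated correlation) and all 18 exocrine pancreas genes (median -1.5, adjusted p = 0.0105; adjusted p = 0.974 with an estimated correlation) had lower differences in ahcy+/- fish. Higher were 15 of 20 leukocyte genes (adjusted p = 0.00569; adjusted p = 0.974 with an estimated correlation), 6 of 9 vitellogenin and oestrogen genes (adjusted p = 0.00605; adjusted p = 0.974 with an estimated correlation) and 19 of 26 fatty acid oxidation genes (adjusted p = 0.015; adjusted p = 0.974 with an estimated correlation). Of these lists 0 members passed over all probe sets or adjusted over the list alone, and 0 lists passed by fry. The omission of overfed ahcy+/- array 4 turned the pancreas (0.00342) and leukocyte lists (0.213) in direction. Leaving out 1 array ended the calls of these lists in 5 of 14 fits for exocrine pancreas (0.381 without regular ahcy+/- array 3), 2 for leukocytes (0.734 without regular ahcy+/- array 8), 3 for oxidative phosphorylation (0.539 without regular ahcy+/+ array 9), 5 for fatty acid oxidation (0.534 without overfed ahcy+/+ array 7), 3 for vitellogenin (0.278 without overfed ahcy+/- array 1) and 1 for skeletal muscle (0.0506 without regular ahcy+/- array 7).

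Vitellogenins, the yolk precursors that the liver makes under oestrogen, varied widely between arrays. Regular-diet ahcy+/+ array 9 stood at 14.56 for vtg2, 13.32 for vtg3 and 13.82 for vtg4, whereas the other 6 regular-diet arrays lay between 5.0 and 5.46, 4.48 and 4.92, and 6.46 and 6.81. Overfed ahcy+/+ arrays lay between 6.71 and 10.64 for vtg2, and overfed ahcy+/- arrays 1 and 4 at 13.46 and 7.30. The probe set shared by vtg5 and vtg6 lay between 8.97 and 13.98 on the 7 overfed arrays, at 14.56 on regular array 9 and between 4.69 and 5.74 on the other regular-diet arrays. With all arrays, its log2 difference between diets in ahcy+/+ fish was 2.96 ± 1.71 (SE; limma adjusted p = 0.366), against 0.46 for vtg2, -0.84 for vtg3 and -0.63 for vtg4, which did not pass either. Without regular array 9 it was 5.34 ± 0.86 (limma adjusted p = 0.00425). The differences of vtg3 (1.34 ± 0.94, adjusted p = 0.462) and vtg4 (1.18 ± 0.95, adjusted p = 0.528) then turned positive and did not pass, nor did that of vtg2 (2.80 ± 1.12, adjusted p = 0.158). The oestrogen receptor gene esr1 stood at 8.5 on regular array 9, between 5.36 and 5.72 on the other regular-diet arrays and between 5.87 and 6.59 on the overfed arrays. Its log2 difference in ahcy+/+ fish was 0.02 ± 0.50 (limma adjusted p = 0.987) with all arrays and 0.76 ± 0.15 (limma adjusted p = 0.0108) without array 9. Array 9 was singled out here after its values were seen, and no high overfed array was dropped with it. Its omission by itself raises the vitellogenin and esr1 differences, so the p-values without it are no test.

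**Figure D4:**
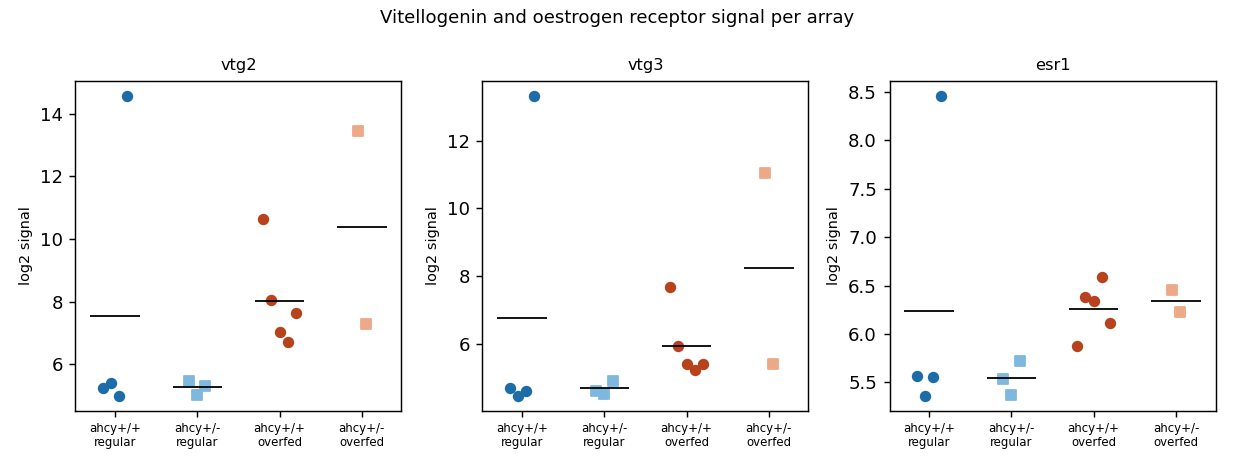
Log2 signal of vtg2, vtg3 and esr1 on each of the 14 arrays, by group, with lines at the group means. Regular-diet ahcy+/+ array 9 stands above its group in all 3 panels (14.56, 13.32 and 8.5), and every overfed array lies above the other 6 regular-diet arrays.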

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

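The counts of other splits for the 2 diet comparisons were chosen before the result was seen; the tests of tissue RNA, tank, carry-over, oestrogen receptor activity and hypoxia and the counts of splits for the genotype comparisons were chosen after it.

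In ahcy+/+ fish, 10 cell cycle genes such as mcm3, mcm4, pcna and rrm1 were lower in overfed livers, among 681 calls between the diets (253 without overfed array 6, 1342 without regular array 9). A chance division of the fish was an unlikely source of that count. Of 100 drawn splits of the 9 ahcy+/+ arrays (126 possible), only 1, the real one, gave as many, and the highest other gave 186. Such splits exchange fish between the tanks, so they cannot address a chance difference between the tanks. RNA from pancreas and intestine in the regular-diet samples stays open as a cause. With both marker levels in the model the median log2 difference of the 10 genes did not shrink. It was -1.59 ± 0.57 (SD), against -1.32 ± 0.54 without them, and all 10 still passed. However, the 10 genes were chosen by their calls in this same comparison. Regular array 9 had the highest intestine mean of all arrays (9.29) and the lowest cell cycle mean on the regular diet (6.14). The marker fit was not repeated without that array, so it cannot decide. The tank stays open: with 1 tank per diet, feeding and any other difference between the tanks cannot be told apart. Less cell cycling after a month of excess food may be the biological explanation, but the design leaves it untested apart from the tank.

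Vitellogenin signal was far above its group on regular-diet ahcy+/+ array 9, and the overfed arrays stood above the other regular-diet arrays. Raised oestrogen receptor activity after overfeeding may account for the latter, but this stays open. The gene esr1, which oestrogen raises in fish liver, differed by 0.76 ± 0.15 (SE, limma adjusted p = 0.0108) in ahcy+/+ fish without array 9. It differed by 0.02 ± 0.50 with that array, and its other probe set by 0.66 ± 0.14 (limma adjusted p = 0.015) without it. Array 9 was singled out after its values were seen, so these p-values are no test. Among overfed ahcy+/+ arrays esr1 did not follow vitellogenin. Array 2 had the highest signal of the probe set shared by vtg5 and vtg6 (12.51) and the lowest esr1 (5.87). Array 6 had the lowest signal of that probe set (8.97) and the highest esr1 (6.59). Carry-over of RNA from array 9, which gives each probe set the same share of its signal there, stays open: 3 of the 5 vitellogenin probe sets, vtg2 among them, lie within 0.14 of the highest value on array 9, and for the other two, vtg4 and vtg3, the ratio of shares had a median of 2.19 over the 7 overfed arrays (1.3 to 3.09), over 2 on 4 of them. The sex of the fish, which the labels do not give, and the tank were not tested.

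The prolyl hydroxylase genes egln3 and p4ha1b were higher in overfed livers of both genotypes (no ahcy+/- call of either without overfed ahcy+/- array 1 or without array 4), which may point to a hypoxia response. A list of 53 other hypoxia genes, 32 measured, was written after the named genes were seen and was higher in overfed ahcy+/+ livers (camera p = 0.0306 with an estimated correlation; 20 of 32 higher, median log2 difference 0.12). Of its members egln1b (1.81) and higd1a (1.82) passed over all probe sets, and 4 higher and 1 lower adjusted over the list alone. Since 13 of the 32 belong to lists already examined, the other 19 were tested after that p was seen. They gave a limma camera p = 0.167 with an estimated correlation, so the explanation is neither excluded nor borne out. The tank, through its water or oxygen, cannot be told apart from the diet here.

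Other samples stood apart from their group in single values, among 12 of 68 gaps tested. For independent gaps chance alone gives about 3.4 (1 in 20). The vitellogenin and esr1 values among the 12 are linked. The shared vitellogenin probe sets and esr1 were named after their values were seen, so the count is no test. On regular-diet ahcy+/+ array 9, mycb was 8.5 against 10.54 to 10.92, the probe set shared by vtg5 and vtg6 14.56 against 4.69 to 5.46, the probe set shared by vtg4, vtg5, vtg6 and vtg7 14.71 against 4.88 to 5.48, vtg2 14.56 against 5.0 to 5.40, vtg3 13.32 against 4.48 to 4.71, vtg4 13.82 against 6.46 to 6.81, and esr1 8.5 against 5.36 to 5.56. In the overfed ahcy+/+ group, nfil3-5 was 10.64 on array 6 against 8.82 to 9.29, and ppdpfa 11.27 on array 7 against 12.18 to 12.54. On array 2 of that group igf2b was 6.22 against 7.59 to 7.94, rbm25a 6 against 5.47 to 5.55, and vtg4 9.52 against 6.99 to 7.48.

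The diet effect differed between the genotypes for 6 gene lists by camera with a preset correlation but for 0 with an estimated correlation or by fry, and 0 genes were past the threshold in limma (289 at an unadjusted p under 0.05). It was lower in ahcy+/- fish for skeletal muscle (adjusted p = 8.71e-05), oxidative phosphorylation (0.00134) and exocrine pancreas genes (0.0105), and higher for leukocyte (0.00569), vitellogenin (0.00605) and fatty acid oxidation genes (0.015). With an estimated correlation the adjusted p was 0.698 for skeletal muscle and 0.974 for the others. The pancreas (0.00342) and leukocyte lists (0.213) turned in direction without overfed ahcy+/- array 4, and the oxidative phosphorylation (0.748) and vitellogenin lists (0.314) did without regular ahcy+/+ array 9 and overfed ahcy+/- array 1, the 2 arrays highest in vitellogenin. Leaving out 1 array ended the calls in 5 of 14 fits for exocrine pancreas (up to 0.381) and fatty acid oxidation (0.534), 3 for oxidative phosphorylation (0.539) and vitellogenin (0.278), 2 for leukocytes (0.734) and 1 for skeletal muscle (0.0506).

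For diet averaged over the genotypes a chance division of the fish was unlikely too, though the splits cannot address a chance difference between the tanks. Only 1 of 100 splits drawn from 1260, the real one, gave as many as the 1564 calls, and the highest other gave 5. The count was 941 without regular ahcy+/- array 3 and 2319 without regular ahcy+/+ array 9. For genotype on the regular diet the real count was 0, which any split reaches (35 of 35), so the splits say nothing on chance. The highest, 122, set ahcy+/+ arrays 2, 5 and 6 with ahcy+/- array 7 against ahcy+/+ array 9 with ahcy+/- arrays 3 and 8, which may point to a structure of the samples other than genotype. No test addressed such a structure, and the split was picked as the highest of splits with a median of 0. The mean of the exocrine pancreas list, compared on that split after it was picked, was 8.59 to 10.7 on the former 4 arrays and 11.63 to 12.45 on the latter 3. For genotype averaged over the diets, the real count was 0 as well, so that 100 of 100 splits drawn from 735 reach it by necessity, and the highest gave 3.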

How the results depend on the processing

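The fits without the 2 arrays highest in vitellogenin, those with pancreas and intestine markers as covariates, and the list tests after quantile normalization or centring were chosen only after the results were seen. The cause was not tested except where stated. No gene chosen by the rule for named genes turned direction under any alternative. Genes named without a call, as between genotypes and in the interaction, count as keeping their side when they stay uncalled. The tally that follows therefore overstates how firm the calls were. Of the values for the genes chosen by the rule and for the first called members of each list, 1669 kept their side of the threshold and 122 lost it. This counts only the lowest and the highest difference of the fits with 1 array left out. Over all those fits, calls were lost in 188 of 952 cases in ahcy+/+, 52 of 154 in ahcy+/- and 47 of 168 averaged. Of the values for single lists 309 kept their side, 179 lost it and 16 turned, with the fits leaving out 1 array counted as 1 value per list. Outside the rule for named genes, vtg3 and vtg4 turned without regular ahcy+/+ array 9, from -0.84 and -0.63 to 1.34 and 1.18 between the diets in ahcy+/+. Probe sets called between diets in ahcy+/+ numbered 1949 with array weights, 1297 with the vitellogenin covariate and 1263 without the 2 arrays, and 253 to 1342 with 1 array left out; array weights gave array 9 a weight of 0.244. In ahcy+/- they numbered 0 with the compared groups alone (fewer arrays), 80 with array weights, 31 after quantile normalization, 64 after centring, 68 with the vitellogenin covariate, 58 without the 2 arrays, 68 with the markers and 0 to 91 with 1 left out. Averaged, they numbered 2810 with array weights, 2460 with the vitellogenin covariate and 538 to 2319 with 1 left out. Between genotypes there were 0 to 0 on the regular diet with 1 left out; after overfeeding 4 without the 2 arrays and 0 to 4 with 1 left out; averaged 2 and 0 to 2; and for the interaction 1 without the low-value filter, 3 without the 2 arrays and 0 to 4 with 1 left out. A lone ahcy+/- overfed array was assumed to vary like the other groups. With the number as a replicate block there were 831, 15 and 1651 diet calls (ahcy+/+, ahcy+/-, averaged) and 0 others. The correlation estimated within blocks was 0.076. Across probe sets the deviations of the same-number samples correlated at -0.084 (number 2), 0.123 (6), 0.098 (3), 0.162 (7) and -0.23 (4). For number 4 the description of the overfed ahcy+/+ sample carries another number. Samples with different numbers were not compared, so these values do not decide whether the numbers pair samples.

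Lists called in ahcy+/+ numbered 17 with the vitellogenin covariate, 0 with an estimated correlation, 4 by fry and 9 to 19 with 1 array left out; in ahcy+/- 0 and 2 by those tests, 9 with the markers and 10 to 15; averaged 20 with the covariate, 0, 5 and 11 to 14. For genotype on the regular diet they numbered 3 after quantile normalization, 3 with the vitellogenin covariate, 0 with an estimated correlation, 0 by fry, 3 without the 2 arrays, 11 with the markers and 3 to 12 with 1 left out; after overfeeding 3, 7, 0, 0, 6, 3 and 1 to 6; averaged 3 after quantile normalization, 0, 0, 2 without the 2 arrays, 13 with the markers and 2 to 7; for the interaction 10 with the covariate, 0, 0 and 3 to 7. With the markers as covariates, their own lists turned by construction: intestine 0.465, 0.76 and 0.534 (ahcy+/+, ahcy+/-, averaged) and exocrine pancreas 0.705 (ahcy+/-), 0.675 (averaged), 0.486 (genotype, regular), 0.552 (genotype averaged) and 0.784 (interaction). With the vitellogenin covariate the vitellogenin list in ahcy+/- turned by construction (0.101), and oxidative phosphorylation in the interaction turned (0.776). Without the 2 arrays the interaction turned for oxidative phosphorylation (0.748) and vitellogenin (0.314). With 1 array left out, exocrine pancreas turned in ahcy+/- (0.625), between genotypes averaged (0.191) and in the interaction (0.00342), and leukocytes in the interaction (0.213), the last pair without overfed ahcy+/- array 4. The highest adjusted p of that pair was 0.381 and 0.734, without regular ahcy+/- arrays 3 and 8. In ahcy+/+, the acute phase (0.13), methionine (0.098) and antioxidant (0.214) lists did not pass with the markers, and antioxidant (0.0615) did not after centring. The ahcy difference ran from 0.07 to 0.14 and from 0.04 to 0.13 (log2) with 1 array left out and was 0.04 and 0.05 after quantile normalization. Only 1 ahcy probe set was measured, so no other was compared. The number of arrays per group, and signal near the low end of the range, limit what could be called.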
